A study of Mus musculus with 149 samples.

How the data were processed

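RNA was measured in 149 single liver cells from 1 mouse. Per the labels, the liver was dissociated by perfusion, hepatocytes were enriched by low-speed spins, cells were captured on Fluidigm C1 chips with 3 trap sizes, and ERCC spike-in RNA was in the lysis mix. The deposited values are a normalised signal: the authors aligned reads with Bowtie 0.12.9 after CASAVA 1.8.2, estimated expected counts with RSEM 1.2.3 on mm10, and deposited 1 table of normalised expected counts with 2 decimals. The name of the deposited table mentions SCnorm, a normalisation method, and WaveCrest, a method for ordering cells; the labels describe neither, nor any filter on cells and genes. Whole read counts cannot be recovered from the table, since the values of a cell fall on several step sizes, so the read depth and its counting error are unknown. The sum of all values of a cell had a median of 1817210 in the large chip, 5678140 in the medium chip and 5539880 in the small chip, spike-ins included.

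The table held 20400 entries, of which 92 were spike-ins and 20308 mouse genes (5453 of them at 0 in all cells). All columns were mapped to the labelled cells and none was left out. No columns were identical, and the median Pearson r between cells on the log2 scale was 0.62, 0.39 and 0.42 in the large, medium and small chips. Genes with a value above 0 in at least 20% of cells (8813) were tested. Of 467 listed symbols, 18 were not matched, 13 of them mitochondrial, so the mitochondrial list was not analysed here, and 3 were matched by an older symbol. Positions are from GENCODE release 21 of the mouse.

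Gene lists, comparisons and most alternatives were chosen before the data were examined. Values were analysed as log2(value + 1) for scores. The landmark score is the mean z-score of 6 pericentral genes minus that of 6 periportal genes, with z-scores within each chip and without the gene being correlated. Each gene received a Spearman rho with the score within each chip, and the mean and SD over the 3 chips are given. A list is described by the median of these means and by its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins; the random range runs over the central 95%. The ends of the score in the large chip are the 16 cells with the lowest and the 16 with the highest score. Middle-lobule genes were averaged over 5 bins of score. Chips were compared as the log2 ratio of mean values with a pseudocount of 1. A cell was counted for another cell type when at least 3 markers of a list were above 0, with exact Clopper-Pearson 95% intervals. No test between groups was run, since cells of 1 mouse are not replicates and each chip is 1 sample; the labels give no batch or date, so 1 run per chip is assumed. No doublet caller was run. Reads of near-identical gene copies (Cyp2c and Mup families) were not separated.

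The genes named were chosen by rule: the 12 landmarks, up to 4 members of each list with the largest mean rho or log2 ratio in size, and up to 10 genes per direction outside the zonation lists or between the large and small chips, with a mean above the median gene. The text quotes the leading ones, and some genes that the rule chose are not reported here. Methods were tested on simulated data made by shuffling cells and planting signals. Of genes planted at a correlation of 0.25, 0.5 and 0.75 with the position, 37.3%, 88.1% and 97.0% met the graded rule, as did 2.14% of the genes with nothing planted. This simulation used all 149 cells, planted the landmarks strongly in every chip and shuffled each gene on its own. It held no shared dependence on the number of genes detected. In the data the landmark sets opposed each other weakly or not at all in the medium and small chips. These rates therefore do not carry over to the data. A planted 2-fold chip difference gave a median log2 of 1.16 and a 4-fold one 2.16; genes with nothing planted ran from -2.35 to 2.62 over their central 95%, so single genes cannot be compared between chips below that size.

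Alternatives covered the pseudocount, rescaling of each cell, Pearson r, pooling of cells, a partial correlation on the number of genes above 0, leaving out cells or chips, other landmarks, a principal component as the axis, and other detection limits. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.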

Results

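The series holds 149 single cells from a preparation of mouse liver hepatocytes, the parenchymal cells of the organ, taken from 1 male C57BL/6 mouse of 8 weeks. The cells were captured on Fluidigm C1 microfluidic chips with 3 ranges of trap size, and each group is named here by its chip. The large chip (17 to 25 µm) gave 80 cells, the medium chip (10 to 17 µm) 30 and the small chip (5 to 10 µm) 39. The title of the series names the recovery of position along the hepatic lobule, the axis from the portal tract, where blood enters (periportal), to the central vein, where it leaves (pericentral). Per the labels all cells come from 1 animal, so cells are not biological replicates. No p-value is given, and every difference below describes these cells. The 3 chips hold cells of different sizes and the labels give no run or date for them, so an SD over chips is a spread between chips and not between repeats.

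The large chip differed from the other 2 in the share of the values taken by the ERCC spike-in, a set of synthetic RNAs added to the lysis mix. In the large chip a median of 7389.5 mouse genes had a value above 0 (range 1371 to 8819) and spike-ins took a median of 3.66% of the summed values (range 1.24% to 92.3%). In the medium chip the medians were 2306.5 genes (1215 to 7846) and 82.7% spike-ins (2.91% to 96.8%), and in the small chip 3087 genes (1488 to 8543) and 82.8% spike-ins (2.36% to 96.6%). Spike-ins took 50% or more in 16 of 80 large-chip cells (20%, exact 95% interval 11.9% to 30.4%), 23 of 30 medium-chip cells (76.7%, 57.7% to 90.1%) and 27 of 39 small-chip cells (69.2%, 52.4% to 83.0%). These intervals, like all intervals on shares of cells below, cover counting error only. The read depth of each cell is unknown because the values are already normalised, and how the normalisation treated chips and spike-ins is not described, so the share is not a direct measure of RNA amount. The main results are therefore given for all 149 cells and, beside them, for the 83 cells with a spike-in share under 50% (64 large, 7 medium, 12 small), a restriction chosen after the data were seen.

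**Figure D1:**
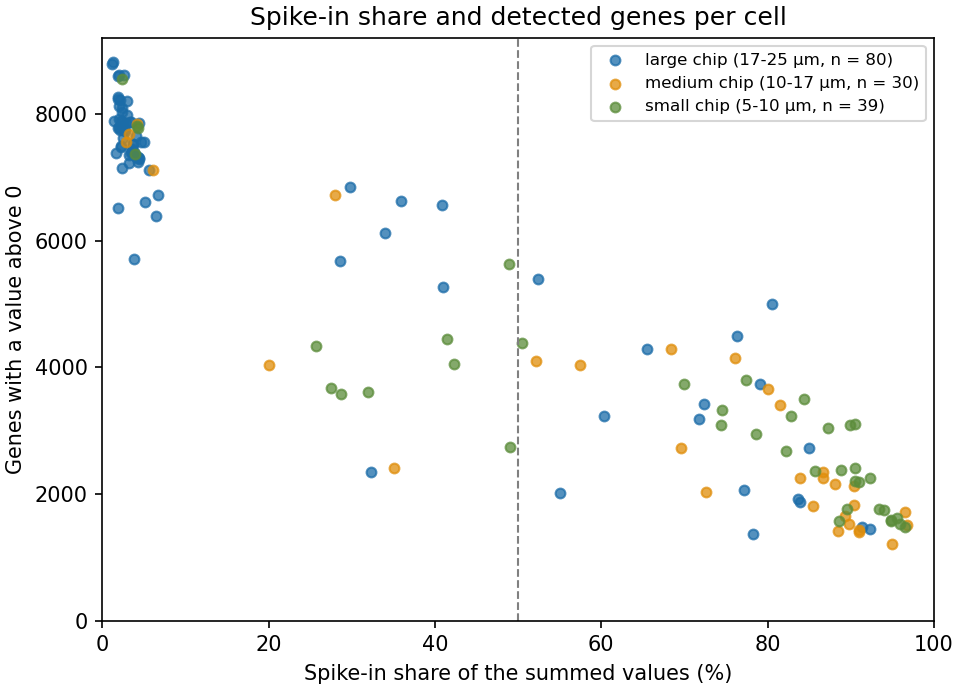
Spike-in share of the summed values of each cell (x axis, percent) against the number of mouse genes with a value above 0 (y axis) for 80 large-chip, 30 medium-chip and 39 small-chip cells. The dashed line marks 50%, which 16, 23 and 27 cells of these chips reached or exceeded.

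The central question was whether single hepatocytes lie along a periportal to pericentral axis. It was addressed with 6 pericentral landmark genes (Glul, Cyp2e1, Cyp1a2, Oat, Gulo and Slc1a2) and 6 periportal ones (Cyp2f2, Ass1, Asl, Hal, Sds and Pck1). Large-chip cells rich in the pericentral landmarks were poor in the periportal ones. Across the 80 cells the Spearman rho between the mean z-scores of both sets was -0.57 (Pearson r -0.69). It was -0.16 (r -0.15) over the 30 medium-chip cells and 0.092 (r 0.028) over the 39 small-chip cells, so the mean of -0.21 ± 0.33 (SD, n = 3 chips) was smaller in size than its spread between chips. Among cells with a spike-in share under 50% the rho was -0.80 in the large chip, -0.25 in the medium chip (7 cells) and -0.57 in the small chip (12 cells), with a mean of -0.54 ± 0.28. The scores also followed the number of genes above 0: the periportal one in the medium and small chips (rho 0.68 and 0.66, against -0.079 in the large chip) and the pericentral one in the large and small chips (0.46 and 0.42, against 0.15 in the medium chip).

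**Figure D2:**
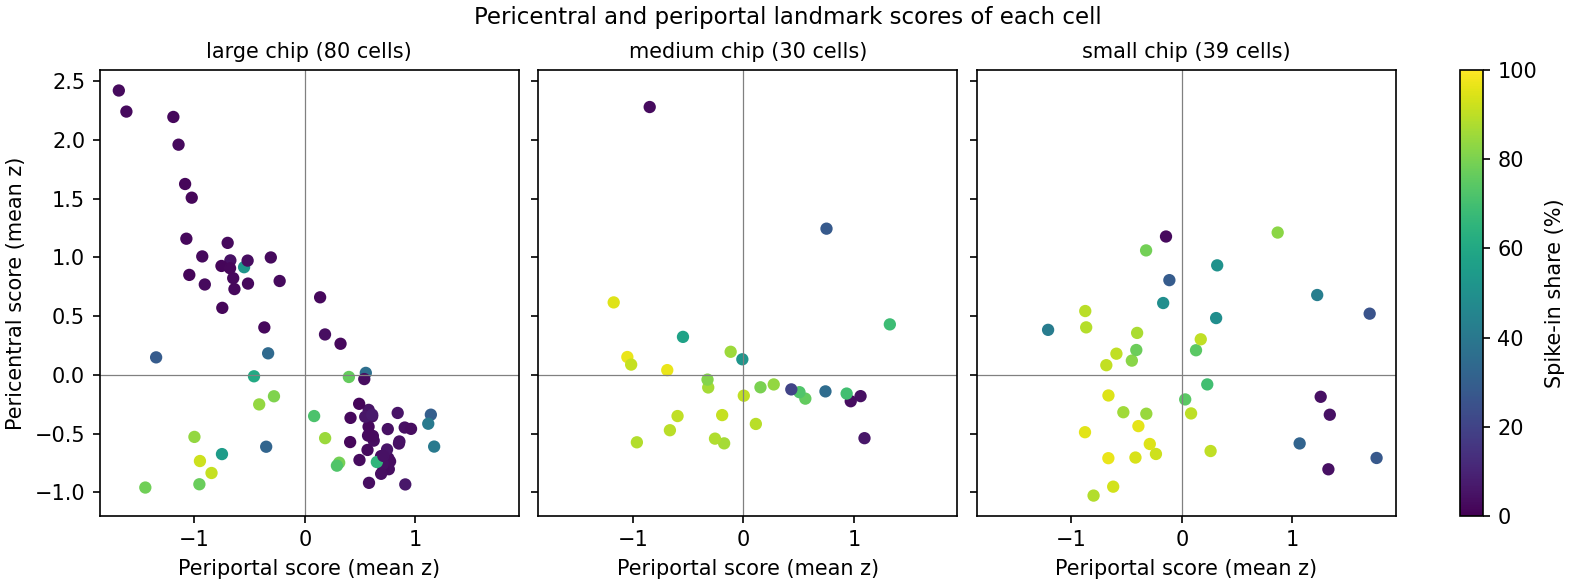
Mean z-score of the 6 periportal landmark genes (x axis) against that of the 6 pericentral landmark genes (y axis) for each cell, 1 panel per chip, coloured by spike-in share. The large-chip cells fall along a descending line (rho -0.57), with its cells of high spike-in share mostly below that line.

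Cyp2e1 and Cyp2f2, cytochrome P450 enzymes of opposite zones, spanned the axis. A landmark score was formed as the pericentral minus the periportal mean z-score, leaving out the gene being examined. In the 16 large-chip cells at the pericentral end of the score Cyp2e1 averaged 15280 ± 7688 (SD over cells), against 54.98 ± 109 in the 16 cells at the periportal end. The periportal cells included cells 24, 53 and 75, with Cyp2e1 at 421, 202 and 65.7. Their summed values were 5563640, 5171760 and 5542320, against a median of 1817210 in the chip. Cell 64, at the pericentral end, had a sum of 5258440. Averages at the ends, here and below, thus rest partly on cells with larger sums, mostly at the periportal end. Cyp2f2 averaged 82.0 ± 210 at the pericentral end and 5206 ± 1265 at the periportal end; most of the pericentral value came from cells 31 and 64 (500 and 718), which also held 11 and 12 endothelial markers at 10 or more. Hal, the histidine ammonia-lyase that opens histidine breakdown, averaged 778 ± 408 at the periportal and 1.27 ± 1.66 at the pericentral end, and Sds, the serine dehydratase, 285 ± 277 and 0.34 ± 0.94. Glul, glutamine synthetase of the hepatocytes around the central vein, averaged 634 ± 1329 at the pericentral and 11.4 ± 19.8 at the periportal end, and the SD above the mean shows that a few cells carried most of it. Oat, ornithine aminotransferase, averaged 1607 ± 1879 at the pericentral and 0.27 ± 0.43 at the periportal end. Cyp2e1 (chromosome 7, 140763739 to 140774987) and Cyp2f2 (chromosome 7, 27119909 to 27133660) are protein-coding genes whose values sum reads over their transcripts; positions here are on mm10, from the GENCODE annotation.

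All 6 periportal landmarks had negative rho with the score in every chip, from -0.34 for Asl to -0.72 ± 0.094 for Cyp2f2 (mean ± SD, n = 3 chips), with Ass1 at -0.51, Pck1 at -0.44, Hal at -0.61 and Sds at -0.57. Of the pericentral landmarks, Oat (0.50 ± 0.34), Cyp2e1 (0.45 ± 0.35), Cyp1a2 (0.45 ± 0.23) and Slc1a2 (0.21 ± 0.15) were positive in every chip. Glul had 0.49, -0.11 and 0.13 in the large, medium and small chips, and Gulo had 0.65, -0.014 and -0.096. Among cells with a spike-in share under 50% Glul (0.65, 0.31 and 0.46) and Gulo (0.72, 0.96 and 0.046) were positive in all 3 chips. There Slc1a2 was negative in the medium chip (-0.61, mean 0.11) and Asl positive (0.21, mean -0.32), and the other 8 landmarks kept their sign in every chip. A gene is called graded below when its rho had 1 sign in all 3 chips and its mean was at least 0.2 in size, a rule of size and not a test. Among cells with a spike-in share under 50% it rests on few medium-chip and small-chip cells (7 and 12). Counts of graded genes there are not directly comparable with those over all cells.

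**Figure D3:**
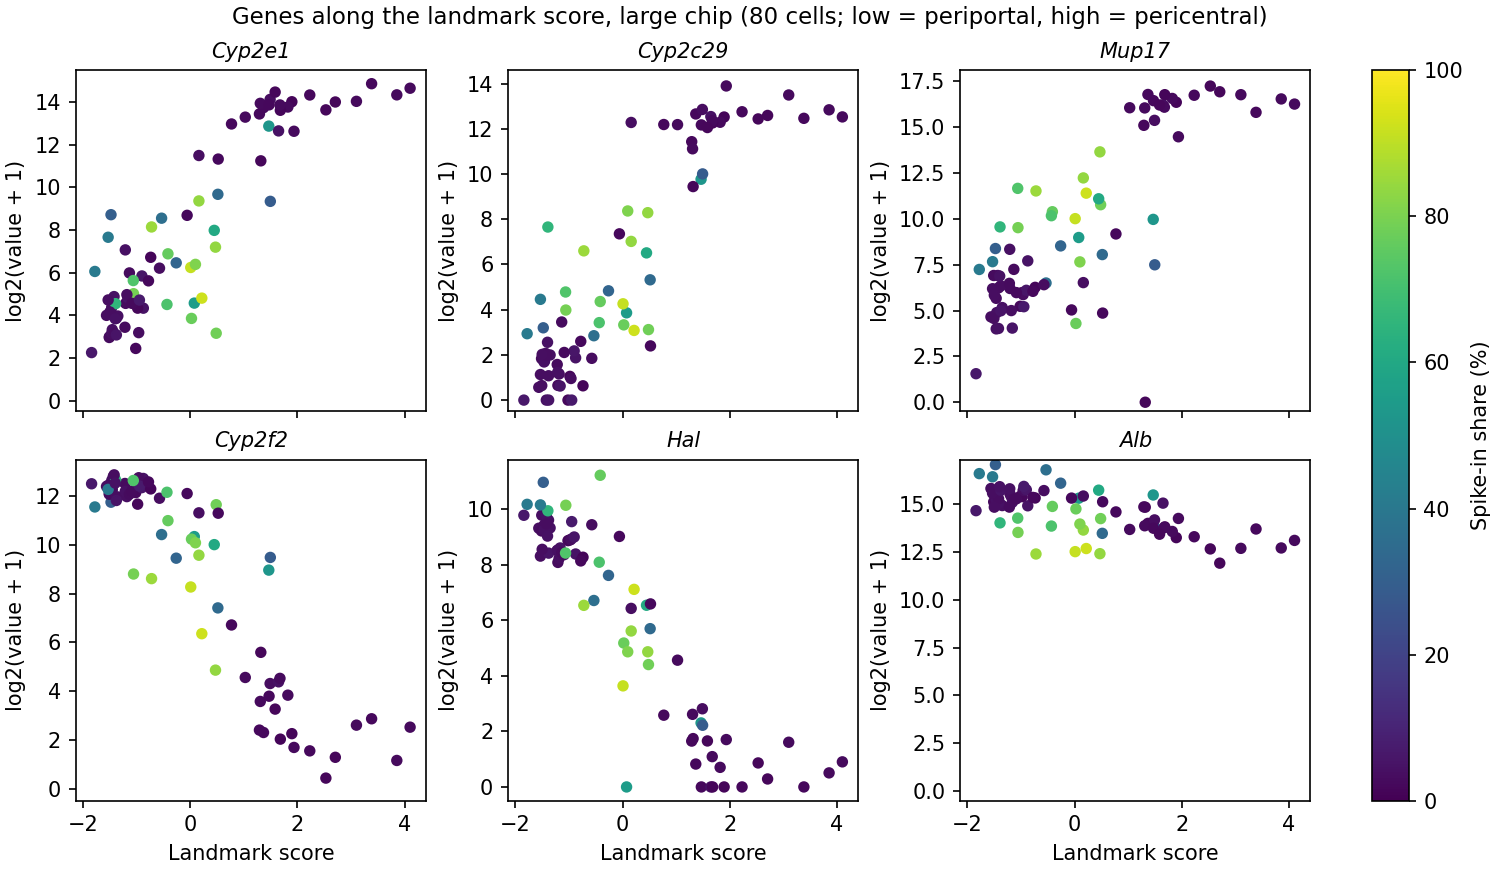
Values of 6 genes on the log2(value + 1) scale (y axes) against the landmark score (x axis, low for periportal and high for pericentral) in the 80 large-chip cells, coloured by spike-in share. Cyp2e1, Cyp2c29 and Mup17 are high at the right, Cyp2f2, Hal and Alb at the left, and Alb remains above 0 in every cell; the score includes Cyp2e1, Cyp2f2 and Hal.

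Genes known to be zonated but kept out of the score followed it in the same directions. Of 23 held-out pericentral genes measured, 11 were graded pericentral, 0 were graded periportal and 12 met neither rule, and 18 of 19 held-out periportal genes were graded periportal. The median rho of the pericentral list was 0.35, above all 10000 random lists of equal size and expression, with medians of 0.68, 0.025 and 0.20 in the large, medium and small chips. The median of the periportal list was -0.45, below all 10000 random lists, with -0.65, -0.42 and -0.34 in the chips. The leading pericentral members were Cyp2c29 (0.64 ± 0.16; 6518 ± 3147 at the pericentral and 3.86 ± 5.10 at the periportal end of the large chip) and Cyp2c50 (0.49 ± 0.27; 2397 ± 1104 and 2.89 ± 4.34). Both belong to a family of near-identical cytochrome P450 genes among which reads may be split, so the level of each copy is uncertain. Hsd17b13, a lipid droplet protein, led the periportal list (-0.58 ± 0.20; 1356 ± 446 periportal and 18.9 ± 31.5 pericentral), followed by Arg1, the arginase of the urea cycle (-0.55 ± 0.18; 2233 ± 1774 and 333 ± 368). Under a spike-in share of 50%, 16 of 23 pericentral and 14 of 19 periportal genes met the rule. With the first principal component of the zonated genes as the axis, the periportal median was 0.092, with 0 of its 19 genes graded periportal. The sign of that axis was set in each chip by Glul, so this direction depends on that choice.

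Over all 8813 genes measured the balance was uneven, with 54 graded pericentral (0.61%) and 1453 graded periportal (16.5%). The median rho of all genes was -0.036, -0.20 and -0.091 in the large, medium and small chips. Once the number of genes above 0 was held constant the counts were 151 and 696, so the balance depended on the number of genes detected. They were 529 and 933 in the cells with a spike-in share under 50%, where the medium and small chips held 7 and 12 cells. With so few cells more genes can meet the rule by chance, and no rate for this was computed. Without the large chip the counts were 79 and 2659, without the medium chip 135 and 1100, and without the small chip 115 and 1991. These last counts asked for 1 sign in fewer chips. Because the balance was uneven, every list is set below against random lists drawn from the same genes.

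Gluconeogenesis, amino acid catabolism and the urea cycle lay on the periportal side, the last 2 through genes that had been chosen as zonated. In amino acid catabolism 15 of 19 genes were graded periportal and 0 pericentral (median rho -0.36, below all 10000 random lists), led by Hal and Sds. In gluconeogenesis, the making of glucose, 8 of 9 genes were graded periportal (median -0.33, percentile 0.105), among them Fbp1 (-0.46 ± 0.18; 3599 ± 1436 at the periportal and 930 ± 488 at the pericentral end) and Pck1. In the urea cycle 5 of 8 were graded periportal (median -0.34, percentile 0.24), led by Arg1 and Ass1 (1516 ± 591 and 452 ± 425). In the cells with a spike-in share under 50% these counts were 12 of 19, 8 of 9 and 2 of 8, and the urea cycle then stood at percentile 6.86. These lists share 7, 3 and 4 genes with the landmarks and held-out zonated genes, Hal, Sds, Pck1, Fbp1, Arg1 and Ass1 among them. Without the shared genes, a comparison chosen after the data were seen, 8 of 12 amino acid genes (median -0.23, percentile 13.9) and 1 of 4 urea cycle genes (median -0.13, percentile 71.1) were graded periportal, inside the random range, and 5 of 6 gluconeogenesis genes (median -0.26, percentile 0.67), outside it.

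Secreted liver proteins were also higher at the periportal end. Of 25 plasma protein genes 24 were graded periportal (median -0.45, below all 10000 random lists), among them Gc, the vitamin D binding protein (-0.57 ± 0.10; 9206 ± 3300 and 3906 ± 1157), and Alb, albumin (-0.57 ± 0.09; 54035 ± 29552 and 12644 ± 7094). The periportal Alb average included cells 24, 53 and 75, with their larger sums, at 136152, 87643 and 98306. Of 16 complement genes 13 were graded periportal (median -0.35, percentile 0.48), led by C8a (1152 ± 611 and 424 ± 197) and C9 (2073 ± 428 and 810 ± 652), components of the membrane attack complex. Genes of hepatocyte identity followed, with 9 of 11 graded periportal (median -0.39, percentile 0.01). Acute phase genes, with 9 of 15 graded periportal and led by Itih4 and Orm1, had a median of -0.24 that lay inside the random range (percentile 15.1). In the cells with a spike-in share under 50%, 5 of 25 plasma protein genes, 5 of 16 complement genes and 2 of 11 identity genes met the rule, with medians of -0.43 (below all 10000 random lists), -0.28 (percentile 3.60) and -0.29 (percentile 2.19).

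Drug-metabolising enzymes divided between the ends. Of 16 genes of cytochrome P450 enzymes and their reductase 7 were graded pericentral and 3 periportal (median 0.35, above all 10000 random lists; 0.69 in the large chip and 0.017 in the medium chip). The list shares 10 genes with the landmarks and held-out pericentral genes, and among the other 6 genes 0 were graded pericentral and 3 periportal (median -0.28, percentile 25.0), so its pericentral side is that of genes chosen as pericentral. Cyp2a12 was among the periportal ones (-0.46 ± 0.07; 610 ± 702 and 182 ± 148). Glutathione transferases had a median of -0.085 (percentile 95.9), with 0 graded pericentral and 3 periportal, and Gstp1, the family's periportal leader, averaged 17985 ± 11117 and 8448 ± 4400. In the large chip alone this list had a median of 0.17, above all 10000 random lists, and -0.26 in the medium chip, so its direction differed between chips. In the cells with a spike-in share under 50% its median was 0.13 (percentile 99.9), with 3 genes graded at each end. Glucuronidating and sulphating enzymes gave 0 pericentral and 2 periportal of 11 (median -0.11, percentile 93.8), with Ugt2b5 at -0.39 and Ugt2b36 at -0.34. Their direction differed between chips too, with 0.15 in the large chip (percentile 99.99) and -0.29 in the medium chip, and in the cells with a spike-in share under 50% the median was -0.19 (percentile 11.1).

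Targets of Wnt signalling, the pathway that marks the pericentral zone, were on the pericentral side (median 0.19, above all 10000 random lists), with 2 of 7 graded, Tbx3 and Rnf43. Tbx3, a transcription factor, had 0.46 ± 0.26 and averaged 70.2 ± 55.02 at the pericentral and 0.038 ± 0.15 at the periportal end. Notum, a Wnt inhibitor, had 0.48 in the large chip, 0.16 in the medium chip and -0.0055 in the small chip. In the cells with a spike-in share under 50%, 5 of the 7 met the rule. Without the 2 genes shared with the landmarks and held-out genes the median stayed at 0.19, above all 10000 random lists, with 1 of 5 graded.

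Among the lipid pathways, cholesterol synthesis and glycolysis with lipogenesis lay on the periportal side. Cholesterol synthesis had 13 of 18 genes graded periportal (median -0.27, percentile 0.01), led by Cyp51 (-0.39 ± 0.11; 210 ± 172 and 108 ± 66.1) and Sqle (-0.37 ± 0.07; 135 ± 139 and 37.3 ± 38.3). Glycolysis and lipogenesis had 8 of 14 (median -0.23, percentile 0.03), led by Acly (247 ± 384 and 26.1 ± 22.7) and Fasn (69.6 ± 49.1 and 41.03 ± 25.9). Fatty acid oxidation, with 8 of 17 graded periportal, stayed inside the random range (median -0.20, percentile 14.7). Bile acid synthesis and transport had 7 of 14 graded periportal, led by Slc10a1 (-0.34 ± 0.25) and Baat (-0.34 ± 0.02), and 1 pericentral, Cyp7a1, the rate-limiting enzyme of bile acid synthesis (0.32 ± 0.32; 339 ± 269 at the pericentral and 4.93 ± 15.8 at the periportal end); its median was -0.24 (percentile 4.17). In the cells with a spike-in share under 50%, glycolysis and lipogenesis had 4 of 14 graded periportal (median -0.15, percentile 3.97, inside the random range), cholesterol synthesis 10 of 18 (percentile 0.03), and bile acids 6 periportal and 2 pericentral (percentile 3.28). In the large chip alone glycolysis and lipogenesis stood at percentile 6.90, cholesterol synthesis at 9.17 and bile acids at 94.9, inside the random range.

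State genes showed little zonation beyond the random lists. Graded periportal were 1 of 15 immediate early genes (Btg2, -0.32 ± 0.05), 5 of 11 heat shock genes, led by Hsp90ab1 and Hspa8, 6 of 11 endoplasmic reticulum stress genes, led by Herpud1 and Calr, 6 of 12 growth hormone targets, led by Mup20 and Igf1, and 0 of 4 cell cycle genes, and 0 in each of these lists were graded pericentral. Their medians, -0.11, -0.19, -0.20, -0.21 and -0.028, all lay inside the random range. Ribosomal protein genes had a median of -0.13 that was higher than 99.35% of random lists, with 2 of 20 graded periportal, Rpl5 (-0.24 ± 0.19) and Rpl10a (-0.21 ± 0.11). In the cells with a spike-in share under 50% the ribosomal median was 0.055 (percentile 99.8), with 0 graded, and the heat shock median 0.040 (percentile 93.5), and the signs of Hsp90ab1 and Rpl5 turned positive.

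**Figure D4:**
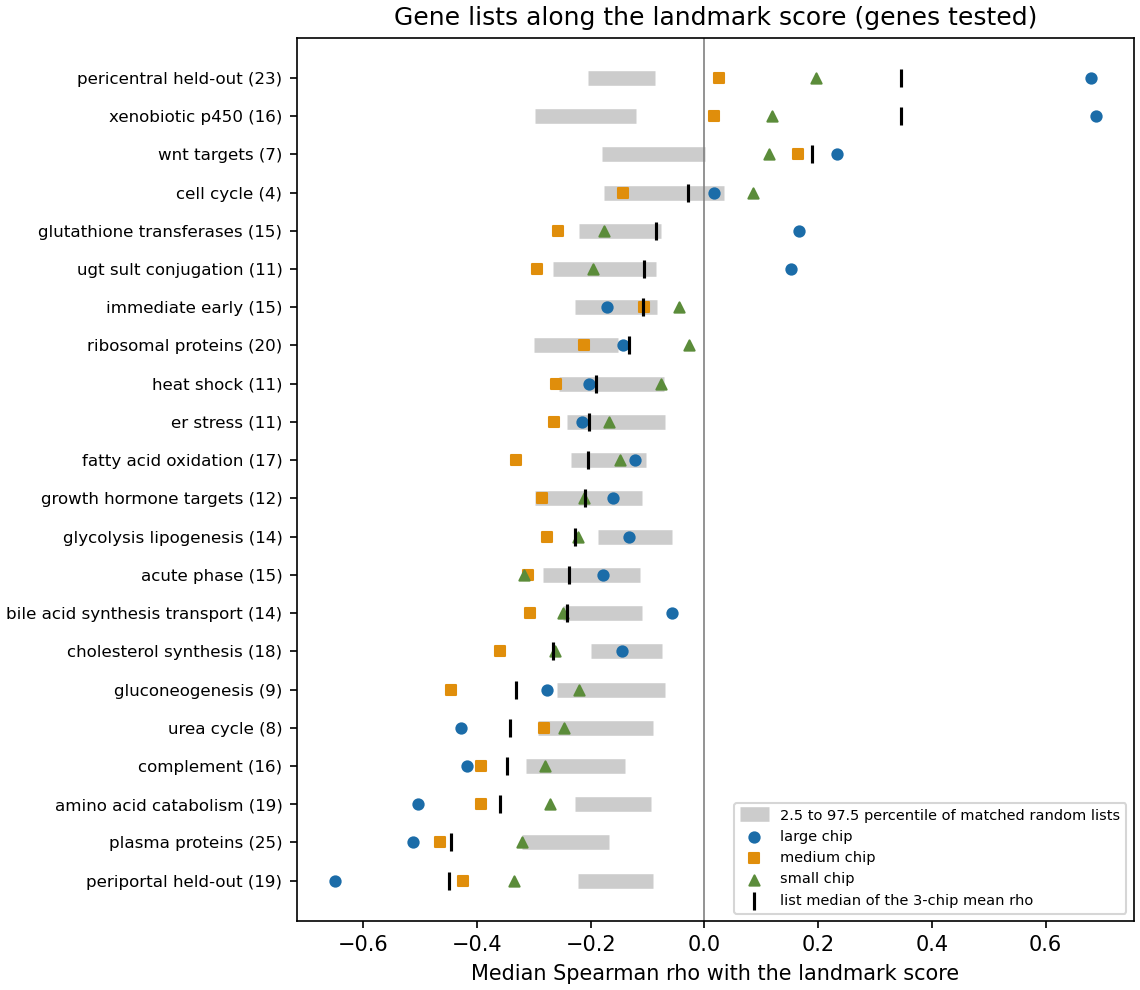
Median Spearman rho with the landmark score (x axis) of each gene list (y axis, genes tested in brackets) in the large, medium and small chips, with the list median of the 3-chip mean rho as a black tick. Grey bars span the central 95% of 10000 random lists matched on expression; the held-out periportal list (-0.45) and the held-out pericentral list (0.35) lie outside on opposite sides.

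Outside the landmark and zonation lists the genes with the highest mean rho were Mup15 (0.60 ± 0.21), Cyp2c67 (0.53 ± 0.24), Mup17 (0.51 ± 0.26), Serpina7, which encodes thyroxine-binding globulin (0.39 ± 0.13), and Hpgd, the 15-hydroxyprostaglandin dehydrogenase (0.37 ± 0.17). Mup17, a major urinary protein (chromosome 4, 61591929 to 61595871, minus strand), averaged 82320 ± 39076 at the pericentral and 87.7 ± 86.6 at the periportal end of the large chip, and Mup15 85357 ± 35897 and 2496 ± 5338. Mup20 lay at the other end (-0.56 ± 0.17; 24951 ± 13408 at the pericentral and 123990 ± 69647 at the periportal end), as did Mup3 (-0.53 ± 0.18; 28157 ± 8353 and 84096 ± 50859). The Mup genes are near-identical copies, so the level of each copy is uncertain. The lowest mean rho outside these lists and the alternative landmarks, which include Alb, were those of Gc, Mup20, Slc3a1, an amino acid transporter subunit (-0.55 ± 0.10; 121 ± 184 periportal and 0.53 ± 1.85 pericentral), Ambp (-0.54 ± 0.13) and C8a (-0.54 ± 0.09).

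Genes reported to peak in the middle of the lobule were examined in 5 bins of landmark score, with 29 or 30 cells each. None of Hamp, Hamp2, Igfbp2, Cyp8b1 and Mup3 was above both outer bins in all 3 middle bins. Hamp, which encodes the iron regulator hepcidin, had mean log2 values of 7.62, 7.22, 7.88, 7.46 and 5.70 from the periportal to the pericentral bin (SD over cells 1.96 to 3.01), and Cyp8b1, a bile acid hydroxylase, had 6.82, 4.96, 4.52, 4.98 and 5.84. The middle bins were also richest in cells with a spike-in share of 50% or more (10.0%, 53.3%, 66.7%, 63.3% and 27.6%). Among cells with a spike-in share under 50%, Hamp (7.47, 7.61, 8.38, 8.47 and 5.10) and Hamp2 (2.75, 2.84, 3.29, 3.87 and 2.09) were above both outer bins in all middle bins. The middle bins averaged 0.68 and 0.58 above the periportal bin, less than the SD over cells. The gap to the pericentral bin was wider.

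The chips were compared to describe what cells each trap size held. Pericentral genes were scarce in the medium chip. The held-out pericentral list had a median log2 ratio of 1.97 for large over medium, above all 10000 random lists, and -1.84 for medium over small, below all of them, whereas the periportal list had -0.34 (percentile 0.20) and 0.66 (percentile 95.8). The landmark score, computed with z-scores over all cells, averaged -0.091 ± 1.51 (SD over cells) in the large chip, -0.47 ± 0.79 in the medium chip and 0.54 ± 0.91 in the small chip. The distance between the small and large chips was 0.64 over all cells and 0.010 among cells with a spike-in share under 50%. For medium minus large these values were -0.37 and -0.72, the latter with 7 medium-chip cells. Each chip is 1 sample, so these differences have no replicate check.

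Levels of most genes were higher in the large chip, with a median log2 ratio of 0.72 for large over small and 0.59 for large over medium over 8813 genes. The ratio for large over small was 0.12 among cells with a spike-in share under 50% (64 and 12 cells, with median mouse-gene sums of 1760470 and 2798040). It was 0.13 in simulated data with all 149 cells shuffled over the chips. The 2 values rest on different numbers of cells, so their closeness does not show that the chips were alike. Among the zonated, pathway and state lists only complement had a median for large over small outside the random range (0.044, percentile 1.01), with Masp1 at -1.58 and C9 at 1.11. Other lists lay below the range in the cells with a spike-in share under 50%, immediate early genes (-1.44, percentile 0.29), cholesterol synthesis (-0.81, percentile 2.18), glycolysis and lipogenesis (-1.14, percentile 2.22) and held-out periportal genes (-0.86, percentile 2.33). The complement list stood at percentile 19.1 there, and turned to the other side of the random median (by 0.17) with a difference of mean log2 values. Among the cell type lists, the cholangiocyte list of 3 genes had 3.34 (percentile 99.9), and 2.18 (percentile 99.2) among cells with a spike-in share under 50%, with Spp1 at 3.94, for which 1 cell gave 57.4% of the large-chip sum, and Sox9 at 3.34. Among the hepatocyte identity genes, with a median of 0.73 (percentile 52.8), Asgr1 had 1.79 and Tat 1.41. Cytochrome P450 genes had 1.78 for large over medium (above all 10000 random lists), with Cyp2c38 at 5.08 for large over small (47.2 against 0.43), and immediate early genes had -0.81 for large over medium (percentile 0.02) and 0.032 for large over small (percentile 4.58), with Gadd45b at 2.95 and Jund at -1.21. Cholesterol synthesis had 0.087 for large over small (percentile 3.40), with Mvd at -2.68 and Fdft1 at -2.40, and the plasma proteins had 0.34 (percentile 4.64), with Plg at -1.25 and Ttr at 1.10. For large over medium the plasma proteins (0.083, percentile 0.295) and glycolysis with lipogenesis (-0.29, percentile 2.35) lay below the random range. For medium over small, cytochrome P450 genes (-1.55, below all 10000 random lists), conjugation genes (-0.81, percentile 0.82) and complement (-0.36, percentile 1.09) lay below it and amino acid breakdown (0.81, percentile 98.5) above it. As differences of mean log2 values Mvd (0.43), Fdft1 (2.19), Plg (1.201) and Masp1 (0.26) had the opposite sign (1 cell gave 96.7% of the small-chip sum of Mvd and 65.6% of that of Masp1). Of the genes in this paragraph only Spp1, Sox9, Cyp2c38, Gadd45b, Mvd and Fdft1 lay outside the central 95% of genes in the shuffled data (-2.35 to 2.62), so no difference between chips is read from the others. The genes were named for the size of their ratio, while that range holds for genes not chosen by size. Lying outside it is therefore no evidence of a difference for Sox9, Cyp2c38 and Gadd45b. No direction is read from Mvd and Fdft1 either, as their sign changed with the difference of mean log2 values, nor from Spp1, which had -6.02 without the cells holding 3 or more markers of another type.

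The most extreme genes between the large and small chips rested on few cells. The 10 genes with the lowest log2 ratio for large over small, headed by Dnajc16 (-5.81; 2.71 against 207), Dus2l (-5.66), Rnf34 (-5.57), Uckl1 (-5.43) and Plcl2 (-5.29), all drew over 50% of their small-chip sum from 1 cell, with a median of 99.6%. Of the 10 with the highest ratio, headed by 1810011O10Rik (6.04; 140 against 1.14), Med7 (5.25), Lgals1 (5.17), Cyp2c38 and Camk2d (5.06), 4 drew over 50% of the large-chip sum from 1 cell. As differences of mean log2 values Dnajc16 (0.27), Rnf34 (0.33), Uckl1 (0.21) and Plcl2 (0.092) had the opposite sign, so no direction between chips is read from these genes.

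Cells with transcripts of other liver cell types were present in all chips. At least 3 of 12 macrophage markers were above 0 in 1 of 80 large-chip cells (1.25%, exact 95% interval 0.032% to 6.77%), 9 of 30 medium-chip cells (30.0%, 14.7% to 49.4%) and 14 of 39 small-chip cells (35.9%, 21.2% to 52.8%). Endothelial markers reached this count in 23 of 80 large-chip (28.75%, 19.2% to 40.0%), 3 of 30 medium-chip (10.0%, 2.11% to 26.5%) and 6 of 39 small-chip cells (15.4%, 5.86% to 30.5%), and cholangiocyte (bile duct) markers in 24 of 80 (30.0%, 20.3% to 41.3%), 0 of 30 (upper limit 11.6%) and 4 of 39 (10.3%, 2.87% to 24.2%). Most of these values were low. In the 70 large-chip cells without 3 markers of another type at 10, Krt7 was above 0 in 60 and Sox9 in 51. Krt19 and Epcam were 0 in all 70, so the cholangiocyte count above 0 does not show bile duct cells. In cells without 3 markers of another type at 10, the macrophage marker Clec4f was above 0 in 0 of 70 large-chip cells. It was above 0 in 4 of 23 medium-chip and 11 of 34 small-chip cells, at 8.71 or less. The macrophage count above 0 therefore does not show macrophages either, and free macrophage RNA was not tested. Cells with at least 3 markers at a value of 10 or more numbered 0, 5 and 2 in the large, medium and small chips for macrophage markers. They numbered 7, 0 and 3 for endothelial, 3, 0 and 0 for cholangiocyte and 0, 2 and 0 for stellate markers. These counts do not show that the cells were of these types. Medium-chip cell 21, counted for macrophage markers, had Clec4f and C1qa at 0 and Alb at 123792. Above 0, 3 stellate markers were found in 1 large-chip and 2 medium-chip cells and 3 lymphocyte markers in 1 large-chip cell. No cell had 3 erythroid or 3 neutrophil markers (0 of 149, upper limit 2.45%).

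The strongest such cells, whose genes are quoted after their values were seen, were distinct. Small-chip cell 1 and medium-chip cell 4 had all 12 macrophage markers at 10 or more, with Clec4f, a Kupffer cell lectin, at 24016 and 11164 and Cd74 at 36900 and 18096, and medium-chip cell 1 had 10 of them. Their Alb values were 2412, 13540 and 17244, against a median of 26918 over the 127 cells without 3 markers of another type at 10. Large-chip cells 7 and 64 and small-chip cell 39 had all 12 endothelial markers at 10 or more, with Clec4g at 17749, 14175 and 7355 and Alb at 11317, 14173 and 5727. Large-chip cells 24 and 71 carried Spp1 at 26143 and 40058 and the bile duct factor Sox9 at 1807 and 1116 together with Alb at 136152 and 112783. The bile duct markers Krt19 and Epcam were 8.75 and 71.4 in cell 24, and both were 0 in cell 71. Cells 24 and 71 also held Cd74 at 789 and 1238 and H2-Ab1 at 638 and 1977. In the 127 other cells these 2 genes reached at most 50.3 and 436. The summed values of cells 24 and 71 were 5563640 and 5568440, against a median of 1817210 in the large chip. Medium-chip cells 5 and 29 carried the stellate genes Dcn (1498 and 948) and Colec11 (7983 and 1045).

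**Figure D5:**
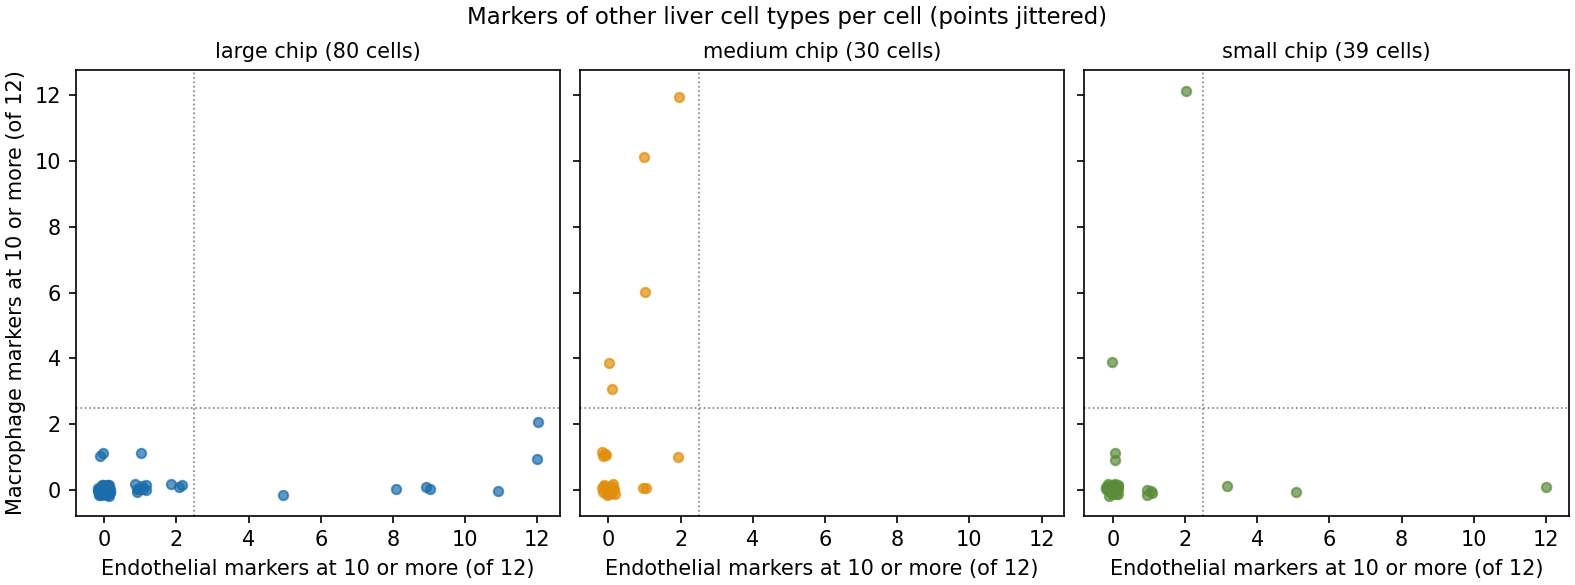
Number of the 12 endothelial markers (x axis) and of the 12 macrophage markers (y axis) with a value of 10 or more in each cell, 1 panel per chip, with points jittered and dotted lines below 3 markers. Cells with at least 3 macrophage markers at 10 lie in the medium and small chips (5 and 2 cells) and those with at least 3 endothelial markers in the large and small chips (7 and 3).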

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

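The restrictions to cells with a spike-in share under 50%, to cells without other markers at 10, to the large chip alone, the lists without landmark and held-out genes and the rescaling to the same mouse-gene sum were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the replicate numbers only count the cells within each chip. The opposition of pericentral and periportal landmarks stayed negative under 14 alternatives (-0.54 to -0.035). The median rho of the held-out pericentral list stayed positive under 19 (0.16 to 0.68). The weakest value of each, -0.035 and 0.16, came without the large chip, so the opposition rested largely on that chip. All values of the opposition lay within the spread between chips (0.33) of the reported -0.21, but that bound is wider than the value itself. The first principal component changed most. With it the held-out periportal list had a median of 0.092 with 0 members graded periportal, 17 held-out pericentral members were graded pericentral, and 2312 genes were graded pericentral and 3 periportal. In the medium and small chips this component followed the number of genes above 0 (rho 0.91 and 0.79) and the spike-in share (-0.92 and -0.82). Its rho with the landmark score was -0.56 and -0.36 there, against 0.95 in the large chip. The sign of a component is arbitrary and was set in each chip by its correlation with Glul, not with the score. In the medium and small chips its direction, and so the sign changes given here, depend on that choice. Genes detected and spike-in share were not separated. Relative to random lists, the first principal component turned cholesterol synthesis (0.027), glycolysis and lipogenesis (0.0071), ribosomal proteins (-0.0075) and Wnt targets (-0.076) to the other side. It also changed the sign of 67 of 109 named genes, among them Cyp2f2 (0.065), Ass1 (0.30), Asl (0.13), Cyp2a12 (0.33), Hal (0.043), Sds (0.054), Pck1 (0.25), Hsd17b13 (0.086), Arg1 (0.17), Mup3 (0.32), Fbp1 (0.24), Acly (0.096), Fasn (0.32), Cyp51 (0.40), Sqle (0.22), Slc10a1 (0.48), Baat (0.32), Gstp1 (0.35), Gsta4 (0.40), Ugt2b5 (0.28), Ugt2b36 (0.26), Gc (0.25), Alb (0.28), Ambp (0.27), C8a (0.31), C9 (0.35), Itih4 (0.25), Orm1 (0.26), Btg2 (0.24), Hsp90ab1 (0.33), Hspa8 (0.30), Herpud1 (0.37), Calr (0.20), Rpl5 (0.37), Rpl10a (0.33), Mup20 (0.21), Igf1 (0.22) and Slc3a1 (0.16). With a spike-in share under 50%, Hsp90ab1 (0.040) and Rpl5 (0.052) changed sign. Without landmark and held-out genes the urea cycle (0.032) and cytochrome P450 (-0.047) lists turned to the other side of their random medians, since the genes left out carried their direction. For the remaining changes the cause was not tested unless given. The 54 genes graded pericentral became 120 with Pearson r, 82 with all cells pooled, 151 with the partial correlation, 84 with other landmarks, 144 among genes above 0 in at least 3 cells, 16 among genes above 0 in at least 50% of cells (fewer genes tested), 529 with a spike-in share under 50%, 489 in the large chip alone, and 79 to 135 without 1 chip. Here and in the counts that follow, pooling, the large chip alone and leaving out 1 chip ask for 1 sign in fewer chips or in none. A spike-in share under 50% leaves few cells in the medium and small chips. Such counts follow a looser rule or vary more. The 1453 graded periportal became 861 with Pearson r, 696 with the partial correlation, 952 with other landmarks, 933 with a spike-in share under 50%, 2817 without cells with other markers at 10, 925 after rescaling to the same mouse-gene sum, and 1100 to 2659 without 1 chip. The 11 held-out pericentral members graded were 6 among genes above 0 in at least 50% of cells and 22 in the large chip alone, where the held-out periportal median was -0.65. Middle-lobule genes above both outer bins numbered 2 with a spike-in share under 50%. The median log2 ratio of all genes for large over small (0.72) was 1.43 as a difference of mean log2 values, 0.39 with a pseudocount of 10, 1.36 after rescaling to the same sum, 0.39 after rescaling to the same mouse-gene sum, 0 by construction after centring, 2.07 with medians over cells, 0.83 without cells with 3 markers of another type, 0.53 among genes above 0 in at least 3 cells and 0.12 with a spike-in share under 50%. Complement lay above its random lists by 0.17 with the difference of mean log2 values. Single genes named between the large and small chips changed sign too: with the difference of mean log2 values Mvd (0.43), Fdft1 (2.19), Plg (1.201), Masp1 (0.26), Dnajc16 (0.27), Rnf34 (0.33), Uckl1 (0.21) and Plcl2 (0.092); with medians over cells Fdft1 (4.61), Plg (2.12) and Masp1 (0.53), while Cyp2c38, Mvd, Dnajc16, Dus2l, Rnf34, Uckl1 and Plcl2 had 0; without cells with 3 markers of another type Mvd (0.38), Dnajc16 (1.67), Rnf34 (0.73) and Uckl1 (1.27); and with a spike-in share under 50% C9 (-0.052). The score of small minus large (0.64) was 0.23 with other landmarks and 0.010 with a spike-in share under 50%, and that of medium minus large (-0.37) was -0.24 after rescaling to the same sum and -0.72 with a spike-in share under 50%. At a value of at least 10 the share of cells with 3 markers was 8.75% for endothelial and 3.75% for cholangiocyte markers in the large chip and 5.13% for macrophage markers in the small chip; with at least 2 markers above 0 it was 50% and 76.25% in the large chip and 53.3% for macrophage markers in the medium chip. The unknown read depth leaves open how far values of 0 reflect detection.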

Other observations

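The tests of the chip-wide amount of spike-in, of cells of other types, of free endothelial RNA and of an endothelial cell captured with a hepatocyte were chosen only after the result was seen; the other 3 were written before theirs. The columns of the deposited table were not in the order of the cell titles. The landmark score followed the column position with rho 0.94, 0.91 and 0.82 in the large, medium and small chips (Pearson r 0.93, 0.89 and 0.85). With the columns split into 5 successive parts, from the first to the last the mean log2 value of Cyp2f2 went from 12.20 to 3.89 and that of Cyp2e1 from 4.14 to 13.29. The labels do not state how the columns were ordered. The name of the table mentions WaveCrest, a method for ordering cells, so the column position is not an independent measure of where a cell lay.

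Most cells of the medium and small chips had over 50% of their summed values in spike-ins. A chip-wide amount of spike-in as the whole cause would leave no cell below a share of 61.3%, and 22 cells lay below it, which argues against it. Cells of other types stay open: 18% of the 50 such cells (9) held 3 or more markers of another type at 10 but 44% (22) above 0, against 15.8% and 52.6% of the 19 cells under 50% in these chips, and Alb was above 0 in all 50 (median 15243). For the same mixture of free hepatocyte RNA in every chamber, a held-out list left its random range among these cells in both smaller chips (2), the bound set against it. These were the periportal list in the medium chip (-0.35, random range from -0.33) and the pericentral list in the small chip (0.14, random range up to 0.11), both narrowly. The other list of each chip stayed inside (percentile 94.2 and 15.8), and in the medium chip it was negative too (-0.13). The periportal score followed the number of genes above 0 in both chips (rho 0.68 and 0.66 over all cells). The test therefore cannot exclude 1 mixture present in varying amounts. Less hepatocyte RNA per chamber, from smaller or damaged cells, or free RNA that varies between chambers, may be the source and was not tested, nor was the normalisation.

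These cells with high spike-in shares also filled the middle of the column order, with 2, 10, 27, 23 and 4 cells in the 5 successive parts. Too few landmark genes detected to place a cell at an end might explain it: the median number of landmarks above 0 was 8 against 10, 7 against 9 and 9 against 10 in the large, medium and small chips, a smallest difference of 1, which meets neither bound set for the test. Cells of the middle lobule might explain it too: the 5 middle-lobule genes stood at percentile 87.5, 69.4 and 98.1 of random lists in the large, medium and small chips, above the random median in each and beyond the random range in 1. For these cells the 2 explanations cannot be told apart, since the position of a cell is known only from the same transcripts.

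Several large-chip cells held endothelial markers together with hepatocyte transcripts. Free endothelial RNA at a level that shows many markers in all chambers is argued against, since 50% of the large-chip cells (40 of 80) had 0 or 1 of the 12 markers above 0. The other 40 cells had 2 or more. Free RNA at a low level would leave many markers at 0, so the test cannot exclude it. An endothelial cell captured with a hepatocyte stays open: median Alb in the 7 cells with 3 or more markers at 10 was 82.3% of that in the other cells with a spike-in share under 50% (29163 against 35441), and each of the 7 had at least 52.7% of the median Alb of the 10 such cells nearest in score. That median was the value of cell 78, which had Clec4g at only 45.87. Only 3 of the 7, cells 7, 31 and 64, had Clec4g at 10% or more of the highest value (17749). Their mouse-gene sums were 3533910, 2573330 and 3756260, against a median of 1760470 in large-chip cells with a spike-in share under 50%. Cell 31 had a share of 52.4%, above that limit. Large-chip cells 17, 24, 53, 71 and 75, with 0 or 1 endothelial markers at 10, had mouse-gene sums of 3808390, 3903320, 3052060, 3564550 and 3279360. A larger sum is thus not particular to cells with endothelial markers and does not by itself point to a second cell. Alb was not scaled for the larger sums, so its values cannot tell a whole hepatocyte from free hepatocyte RNA. A pair of cells may account for these 3, and an endothelial cell with free hepatocyte RNA was not tested. A hepatocyte with some endothelial RNA could also give the other 4. No image of the chambers was used here.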
